A study of Mus musculus with 12 samples.

How the data were processed

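RNA was extracted from pieces of pancreatic tumor with the PureLink kit, and preparations with an RNA integrity number above 8 went on to poly(A) selection and a strand-specific NEBNext Ultra Directional library, per the labels' protocols. Reads were trimmed with cutadapt 2.3, aligned to the mouse genome build mm10 with STAR 2.7.0d and quantified with RSEM 1.3.1, per the submitters' processing notes. The annotation and the strand setting used in that quantification are not given in the sources used here. The authors deposited expected counts and TPM (transcript abundances scaled to a fixed sum) for 47643 genes in 12 libraries. The deposited expected counts were whole numbers for 86.0% to 88.2% of entries in a library, with a tolerance of 0, and were rounded before testing. The deposited TPM values entered only as an alternative. RSEM shares reads among genes of similar sequence, so values of immunoglobulin, histone and other multigene families are uncertain.

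Each library was placed in the Young tumor or Old tumor group by its label, with 6 libraries in each. Replicate numbers run through both groups without a stated link between libraries of the same number, so the main model had no block. Library totals ran from 17.8M to 24.1M counts.

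The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment over the 16013 genes that passed the filter, two-sided, at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Every fold change is old over young. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2.

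Gene lists for cell types and pathways that a pancreatic tumor can hold, 39 in all, were fixed before the data were examined, as were the model, the tests, the alternative settings and the rule for naming genes. A list's score in a library is the mean log2 CPM of its tested members. Group means were compared by a two-sided exact permutation test over the 924 ordered splits of 12 libraries into 6 and 6, whose smallest p is 0.00216, with Benjamini-Hochberg adjustment over 37 lists. At least 3 tested members were required, which left out skeletal muscle with 2, and the sex-linked genes served only as a check of the libraries. With 37 lists, a single list at the smallest p has an adjusted p of 0.080 unless other lists have small p too. Beside this test ran camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated one, and fry. Where a symbol had several IDs, the most abundant was used. Older names in the table stood for Cd244a (Cd244), Ccn2 (Ctgf) and Ero1a (Ero1l), and Ahsp had no match. Correlations of list scores used permutation tests with 100000 resamples over 12 libraries and exact permutation within a group of 6 (scipy 1.17.1).

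Named genes are the 12 with the largest fold change in each direction among genes past the threshold with a mean of at least 1 CPM, an official symbol that is not a predicted or clone name, and at least 5 of 6 libraries of each age beyond the other age's median. The 4 members with the smallest p were added for each list described in detail. Genes named in the closing section outside this rule were chosen after their values were seen.

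Exon lengths, GC content and coordinates came from a GENCODE annotation of GRCm38, the assembly of mm10. It held 47224 of the 47643 gene IDs and 15971 of the 16013 tested ones (99.7%). The length correction fits, in each library, a natural spline with 4 degrees of freedom to each gene's deviation from the mean of all libraries and enters the fit as an offset.

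The alternatives set beforehand were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter and a stricter one of 1 CPM in 6 libraries, TPM values with pseudocounts of 1 and 0.1, an acinar score as a covariate, a replicate block, other thresholds and each library left out. Corrections for length and GC content, lists limited to members of at least 1 CPM, and a fit without Old tumor 1 and Old tumor 5, which lay far out on principal components, were added after the data were seen. Young tumor 2, at 53.5 on the third component, and Old tumor 4, at 41.7 on the first, lay far out too. These 2 were left out only 1 at a time.

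The scripts were tested on simulated data drawn from the real means, dispersions and library sizes. For the comparison of old with young tumors over 16013 genes, the edgeR test recovered 44%, 82%, 92% and 96% of genes changed by 1.5-fold, 2-fold, 4-fold and 8-fold, and 6.55% of its calls were unchanged genes. Unchanged genes given the measured length slopes yielded 0 calls with edgeR. That simulation had linear slopes, independent genes and dispersions that already held length spread within an age. It therefore does not show that the trend made no calls in the real data, where 98 of the 362 calls passed with the length correction too. A simulated list shifted by 1 on the log2 scale was measured at 1.02, and 0 other lists were called by exact permutation. The reads themselves were not analysed here.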

Results

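Bulk poly(A) RNA sequencing covered 12 pieces of pancreatic tumor grown in mice from KPC4662, a mouse pancreatic ductal adenocarcinoma cell line. The 6 Young tumor and 6 Old tumor libraries differed by the age group of the mouse that carried the tumor. The labels used here give neither the ages nor the strain, sex or route of implantation. They also leave open whether each piece came from its own mouse, so every p-value here measures the spread between these pieces. Library totals ran from 17.8M counts in Old tumor 6 to 24.1M in Old tumor 5. Young libraries held 21.9 ± 1.13M counts (SD, n = 6) and old libraries 22.6 ± 2.41M (SD, n = 6), a difference within the spread (two-sided exact permutation p = 0.528). Xist, the transcript that silences an X chromosome in female cells, had 18973 to 46825 counts per library. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at most 2 counts in any library. Every pair of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of at least 16.7, so each counted as a separate sample. The first principal component took 18.7% of the variance and did not separate the ages (two-sided exact permutation p = 0.955), with Old tumor 1 farthest out at −55.0. The second took 16.4% and separated them, at 20.7 ± 8.38 in young and −20.7 ± 12.9 in old libraries (SD, n = 6 each; two-sided exact permutation p = 0.00216, the smallest this design allows).

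The comparison of old with young tumors asked how the tumor transcriptome differed with the age of the host, which the series title connects to exclusion of immune cells. Lists of mitotic genes and of nuclear-encoded subunits of the respiratory chain were lower in old tumors by exact permutation, with 9 and 6 of 25 members past the threshold over all genes. Neither list passed camera with an estimated correlation between genes (adjusted p = 0.36 for both), a test that sets a list against all other genes. Both passed fry, which tests the members alone (adjusted p = 0.031 and 0.0065). The cytotoxic granule protease gene Gzma was lower by 4.42-fold. The immunoglobulin M heavy chain gene Ighm was higher by 42.5-fold (log2 fold change 5.41, and 4.51 without Old tumor 1), and the collagen receptor gene Itga11 and the collagen gene Col12a1 were higher by 3.09-fold and 1.95-fold, though Col12a1 did not pass with a correction for gene length. With edgeR's quasi-likelihood test, 362 of 16013 tested genes passed an adjusted p of 0.05, 127 of them higher and 235 lower in old tumors. Protein-coding genes made up 340 of the 362. Most changes were small: 14 of the higher and 5 of the lower genes changed by at least 2-fold, and the median log2 fold change was 0.47 among the higher and −0.41 among the lower genes. An unadjusted p under 0.05 was reached by 3381 genes, against 801 expected by chance. Higher genes made up 35.1% of the calls, but 51.5% when libraries were scaled by total counts alone, and 85.8% and 87.6% on log2(TPM + 1) and log2(TPM + 0.1), where the median of all genes lay at 0.13 and 0.15 in place of 0.03. The count rested on single libraries, with the filter applied anew each time. It fell from 362 to 2 without Old tumor 3, 9 without Young tumor 1, 12 without Old tumor 2, 27 without Old tumor 5, 41 without Old tumor 4, 41 without Old tumor 6, 52 without Young tumor 4, 52 without Young tumor 5, 85 without Young tumor 2 and 120 without Young tumor 6. It rose to 471 without Young tumor 3 and to 1106 without Old tumor 1. With all libraries, 1 gene passed with the acinar score, itself lower in old tumors, as a covariate, and 1 with a replicate block.

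The 12 genes with the largest increases were led by immunoglobulin genes. Ighm (ENSMUSG00000076617; chromosome 12, 113418558 to 113422730, mm10) was at 6.23 ± 4.35 CPM (counts scaled to library size) in young and 266 ± 322 CPM in old tumors (SD, n = 6 each), a log2 fold change of 5.41 (SE 0.87, edgeR adjusted p = 0.024). All 6 old libraries lay above the young median, and without Old tumor 1 the log2 fold change of Ighm was 4.51. The kappa light chain variable gene Igkv3-2 had a log2 fold change of 6.94 (SE 1.44, edgeR adjusted p = 0.035), which was 5.26 without Old tumor 1 and 8.26 without Young tumor 5, and its reads can be shared with related variable genes. Plin4 (ENSMUSG00000002831; chromosome 17, 56100591 to 56109803), which codes for a lipid droplet coat protein of adipocytes, rose by 2.27 on the log2 scale (SE 0.48, edgeR adjusted p = 0.035). Itga11 (ENSMUSG00000032243; chromosome 9, 62677826 to 62783982), the integrin alpha 11 collagen receptor of fibroblasts, rose from 1.10 ± 0.43 to 3.41 ± 1.38 CPM (SD, n = 6 each; log2 fold change 1.63, SE 0.32, edgeR adjusted p = 0.033). Fmod and Prelp, small leucine-rich proteoglycans that bind collagen, rose by 1.24 (SE 0.26) and 0.86 (SE 0.19). Col12a1, a fibril-associated collagen, rose from 79.2 ± 10.2 to 154 ± 51.9 CPM (SD, n = 6 each; log2 fold change 0.96, SE 0.20), and with the length trend removed its log2 fold change was 0.77 (SE 0.19, edgeR adjusted p = 0.080). The homeobox genes Hoxb3 and Onecut3 rose by 1.40 (SE 0.28) and 0.75 (SE 0.18). Airn, the antisense transcript of the imprinted Igf2r locus, rose from 2.96 ± 0.72 to 5.94 ± 1.53 CPM (SD, n = 6 each), with reads that overlap its partner on the other strand. Slc25a42, a mitochondrial coenzyme A carrier, and Pdpr, the regulatory subunit of pyruvate dehydrogenase phosphatase, rose by 0.86 (SE 0.19) and 0.75 (SE 0.15). The naming rule required at least 5 of the 6 old libraries to lie above the young median, so that holds for each by selection. With the length trend removed Airn, Slc25a42, Onecut3 and Pdpr lost their calls as Col12a1 did (edgeR adjusted p = 0.052, 0.079, 0.089 and 0.066). Log2 fold changes of Airn, Slc25a42, Onecut3 and Pdpr were then 0.992, 0.79, 0.72 and 0.70, against 1.002, 0.86, 0.75 and 0.75 before.

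Among the 12 genes with the largest decreases were genes of cytotoxic lymphocytes and of cell division. Gzma (ENSMUSG00000023132; chromosome 13, 113093825 to 113100981), granzyme A of cytotoxic T and natural killer cells, fell from 8.47 ± 4.18 to 1.91 ± 1.54 CPM (SD, n = 6 each; log2 fold change −2.14, SE 0.45, edgeR adjusted p = 0.035). Cd7, a surface protein of T and natural killer cells, fell by 1.63 on the log2 scale (SE 0.36, edgeR adjusted p = 0.040). Ube2c (ENSMUSG00000001403; chromosome 2, 164769898 to 164778822), the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 73.8 ± 12.5 to 40.7 ± 7.58 CPM (SD, n = 6 each; log2 fold change −0.86, SE 0.14, edgeR adjusted p = 0.024). The mitotic kinase genes Aurka and Nek2 fell by 0.75 (SE 0.12) and 0.72 (SE 0.15). Rrm2, a subunit of ribonucleotide reductase, fell from 50.9 ± 3.78 to 31.1 ± 6.12 CPM (SD, n = 6 each; log2 fold change −0.71, SE 0.12). Cdkn3, a phosphatase that acts on cyclin-dependent kinases, Birc5, which codes for survivin, and Fam64a, a mitotic regulator, fell by 0.92 (SE 0.19), 0.68 (SE 0.14) and 0.71 (SE 0.16). The histone gene Hist1h2ap fell by 1.13 (SE 0.23), with reads that near-identical histone copies can share. Mfsd2a, a lysolipid transporter, and Tspan11, a tetraspanin, fell by 0.87 (SE 0.21) and 0.91 (SE 0.22). For each of these 12 genes, all 6 old libraries lay below the young median. With the length trend removed Cd7, Hist1h2ap, Tspan11, Mfsd2a and Fam64a lost their calls (edgeR adjusted p = 0.058, 0.072, 0.053, 0.079 and 0.058). Their log2 fold changes were then −1.55, −0.98, −0.98, −0.85 and −0.71, against −1.63, −1.13, −0.91, −0.87 and −0.71 before.

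**Figure D1:**
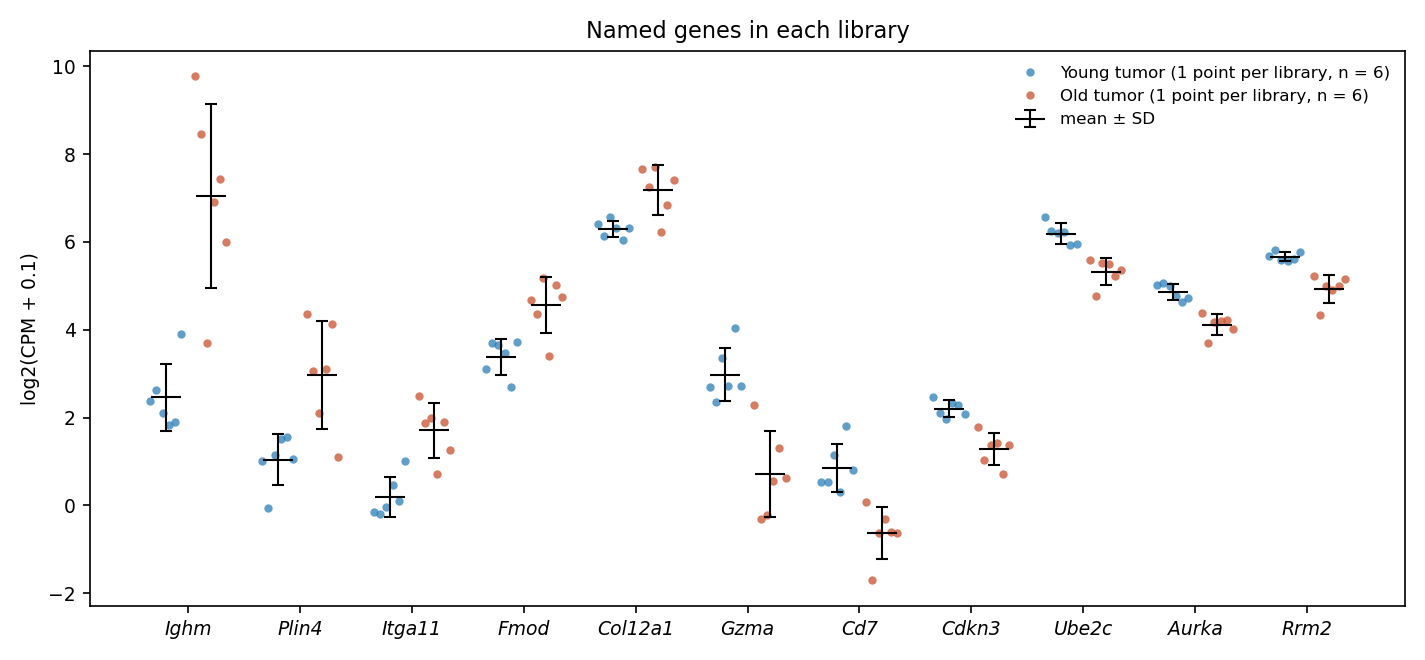
Expression of 11 of the named genes as log2(CPM + 0.1) in each of the 12 libraries, with 1 point per library and bars for the mean ± SD of 6 libraries. Ighm had 6.23 CPM on average in young and 266 CPM in old tumors, with a wide spread among the old ones, while Rrm2 and Aurka separated the ages with little spread.

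Gene length moved with age across the whole transcriptome. Long genes were higher and short genes lower in old tumors: the median log2 fold change ran from −0.18 in the shortest length decile (83 to 1334 bp of exon) to 0.16 in the longest (9469 to 123179 bp). Slopes on log2 exon length were fitted to each gene's deviation from the mean of all 12 libraries. They were −0.0348 ± 0.0303 in young and 0.0348 ± 0.0315 in old libraries (SD, n = 6 each, two-sided exact permutation p = 0.00649). That centering makes the group means equal and opposite, so only their difference is informative. The ages overlapped, with Young tumor 2 at 0.0114, above Old tumor 1 (0.0027) and Old tumor 4 (−0.0016). Genes higher in old tumors had a median exon length of 9210 bp and lower genes one of 2003 bp, against 4022 bp for all tested genes. With the length trend removed from each library, 15 genes passed as higher and 97 as lower, including 15 of the 127 and 83 of the 235. The median log2 fold change of the 127 higher genes went from 0.47 to 0.33 (median SE 0.10 and 0.097), and that of the 235 lower genes from −0.41 to −0.38 (median SE 0.086 and 0.090).

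**Figure D2:**
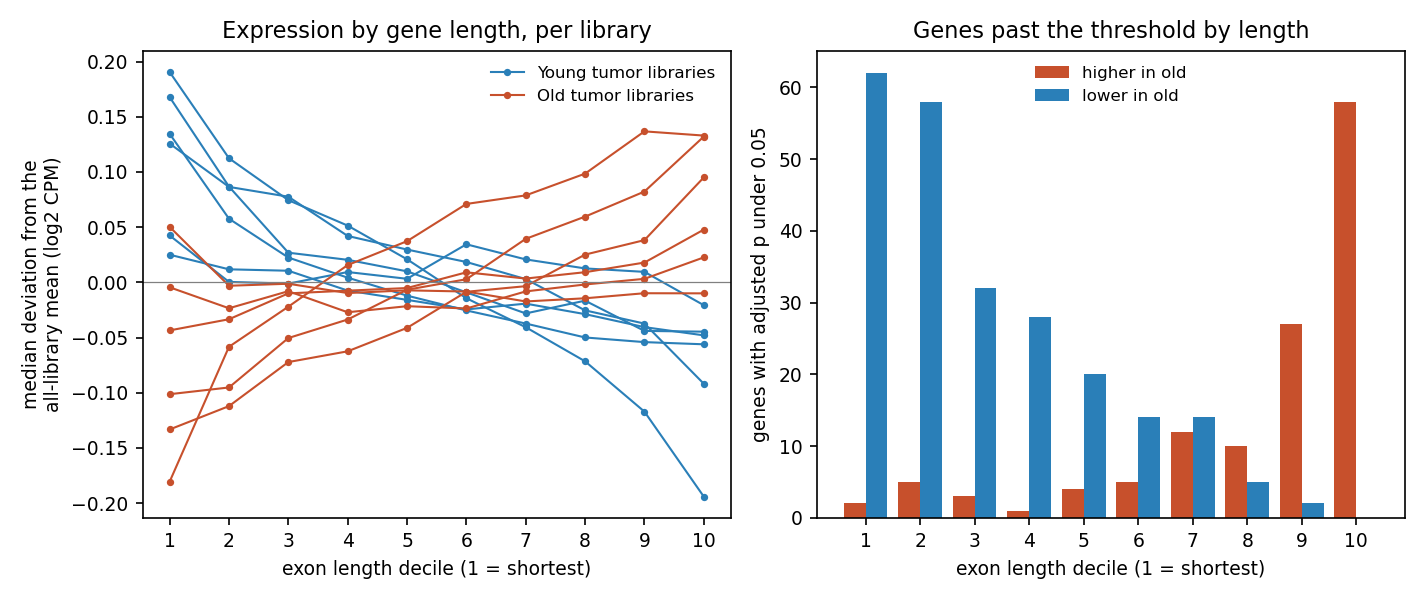
Left, median deviation of each length decile from the mean of all 12 libraries (log2 CPM), 1 line per library, against exon length decile from shortest to longest. Right, number of genes past the threshold in each decile, with 62 lower and 2 higher genes in the shortest decile and 0 lower and 58 higher genes in the longest.

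Genes of DNA replication and mitosis were lower in old tumors as a group. The cell cycle list averaged 5.60 ± 0.161 log2 CPM in young and 5.14 ± 0.226 in old tumors (SD, n = 6 each), a difference of −0.46 (two-sided exact permutation p = 0.00216, adjusted p = 0.040), with all 6 old libraries below the young median. Camera with an estimated correlation between genes, which sets a list against all other genes, did not call it (adjusted p = 0.36), while fry did (adjusted p = 0.031). All 25 members had a fold change below 0. Of these, 9 fell over all genes tested and 19 fell when adjusted over the list alone. Aurka fell from 29.3 ± 3.67 to 17.5 ± 2.73 CPM (SD, n = 6 each) and Cdk1, the kinase that drives entry into mitosis, from 51.8 ± 7.02 to 33.8 ± 5.78 CPM (log2 fold change −0.62, SE 0.12, edgeR adjusted p = 0.033), beside Ube2c and Rrm2. Members had a median exon length of 4059 bp, close to that of all genes, and the difference was −0.49 with the length trend removed (two-sided exact permutation, adjusted p = 0.040). The call was also lost without Young tumor 2 (−0.43, adjusted p = 0.080) and without Old tumor 2 (−0.38, adjusted p = 0.080), both by exact permutation. Total counts (−0.43, adjusted p = 0.080), TPM (−0.30, adjusted p = 0.160) and medians over members (−0.46, adjusted p = 0.080) ended it too by exact permutation.

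Nuclear-encoded subunits of the respiratory chain and ATP synthase were lower in old tumors by a smaller and tighter margin. The oxidative phosphorylation list averaged 6.77 ± 0.0779 log2 CPM in young and 6.51 ± 0.0729 in old tumors (SD, n = 6 each), a difference of −0.25 (two-sided exact permutation p = 0.00216, adjusted p = 0.040), with all 6 old libraries below the young median. Camera with an estimated correlation did not call this list either (adjusted p = 0.36), while fry did (adjusted p = 0.0065). All 25 members had a fold change below 0, 6 fell over all genes tested and 17 fell when adjusted over the list alone. Cox5b, a subunit of cytochrome c oxidase, fell from 76.9 ± 2.78 to 56.9 ± 4.10 CPM (SD, n = 6 each; log2 fold change −0.44, SE 0.062, edgeR adjusted p = 0.014). The complex I subunit genes Ndufb3 and Ndufa1 fell by 0.47 (SE 0.078) and 0.44 (SE 0.10), and the ATP synthase gene Atp5o by 0.31 (SE 0.072). The mitochondrially encoded genes differed by −0.06 (two-sided exact permutation p = 0.716), and their share of counts was 4.28% ± 0.871 in young and 4.23% ± 0.523 in old tumors (SD, n = 6 each). Members of the nuclear list were short, at a median of 2178 bp, and their difference was −0.22 with the length trend removed (two-sided exact permutation, adjusted p = 0.040). By exact permutation the call was also lost without Young tumor 2 (−0.25, adjusted p = 0.080), Old tumor 2 (−0.26, adjusted p = 0.080) or Old tumor 4 (−0.26, adjusted p = 0.053). The difference itself did not shrink there. Total counts (−0.22), TPM (−0.13) and medians over members (−0.28) ended it too, each with an adjusted p of 0.080 by exact permutation. Without Old tumor 2 the smallest unadjusted p of any list was 0.00433 by exact permutation. In the other settings named here it was still 0.00216, though not always for this list. A single list at 0.00216 has an adjusted p of 0.080 unless other lists have small p too.

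Markers of T cells, cytotoxic lymphocytes and antigen presentation lay lower in old tumors on average, but none of these lists passed adjustment over the 37 lists tested. The cytotoxic and natural killer cell list differed by −0.84 (two-sided exact permutation p = 0.0152, adjusted p = 0.187), with all 6 old libraries below the young median. Of its 18 genes 10 passed the filter and were tested, 8 below 0 and 2 above. Among these Gzma fell over all genes, and 2 fell when adjusted over the list alone: Gzma and the chemokine gene Xcl1 (log2 fold change −2.17, SE 0.53). Klre1 and the granzyme gene Gzmb were at −1.29 (SE 0.48) and −1.28 (SE 0.50) and did not pass. The MHC class I presentation list differed by −0.76 (two-sided exact permutation p = 0.0303, adjusted p = 0.214), with all 6 old libraries below the young median and all 18 members below 0. The immunoproteasome subunit gene Psmb10 fell by 0.59 (SE 0.12, edgeR adjusted p = 0.035) and the proteasome activator gene Psme2 by 0.46 (SE 0.11, edgeR adjusted p = 0.044). When adjusted over the list alone 11 members fell, among them Psme1 (−0.34, SE 0.087) and B2m, the light chain of every MHC class I molecule (−0.93, SE 0.28).

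The MHC class II presentation list differed by −0.53 (two-sided exact permutation p = 0.0260, adjusted p = 0.214). None of its 10 members passed over all genes with edgeR, and 6 fell when adjusted over the list alone. The invariant chain gene Cd74 was at −0.55 (SE 0.17), and the peptide exchange genes H2-DMb1, H2-DMb2 and H2-DMa at −0.84 (SE 0.23), −0.68 (SE 0.21) and −0.58 (SE 0.18). The T cell list differed by −0.64 (two-sided exact permutation p = 0.0844, adjusted p = 0.320), with 21 of 22 members below 0 and none past the threshold over all genes or when adjusted over the list alone. Cd8a went from 6.29 ± 2.61 to 2.59 ± 1.70 CPM and Cd4 from 5.12 ± 1.28 to 3.05 ± 1.03 CPM (SD, n = 6 each), with Skap1 at −0.96 (SE 0.31) and Cd3d at −1.24 (SE 0.44). The checkpoint and exhaustion list differed by −0.48 (two-sided exact permutation p = 0.0411, adjusted p = 0.217), where Cd160 (−1.07, SE 0.29) was the member that fell when adjusted over the list alone, and Pdcd1, which codes for PD-1, was at −1.19 (SE 0.43). Lag3 and Tox, its other members of smallest p, were at −0.46 (SE 0.19) and −0.59 (SE 0.29). The interferon gamma response list differed by −0.80 (two-sided exact permutation p = 0.0887, adjusted p = 0.320), with all 21 members below 0, none of them past the threshold over all genes or when adjusted over the list alone. Ido1 and Tgtp2 were at −1.02 (SE 0.37) and −1.28 (SE 0.53), Irf1 and Gbp8 at −0.35 (SE 0.15) and −0.45 (SE 0.21). Without Old tumor 1, the library with the highest T cell score of its age group, the cytotoxic (−1.01, adjusted p = 0.048), MHC class II (−0.69, adjusted p = 0.040) and checkpoint (−0.66, adjusted p = 0.027) lists passed by exact permutation. Without Old tumor 2 the cytotoxic list differed by −0.51 (exact permutation, adjusted p = 0.374). On log2(TPM + 1) the T cell list differed by −0.32 and the checkpoint list by −0.20 (exact permutation, adjusted p = 0.418 and 0.424).

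**Figure D3:**
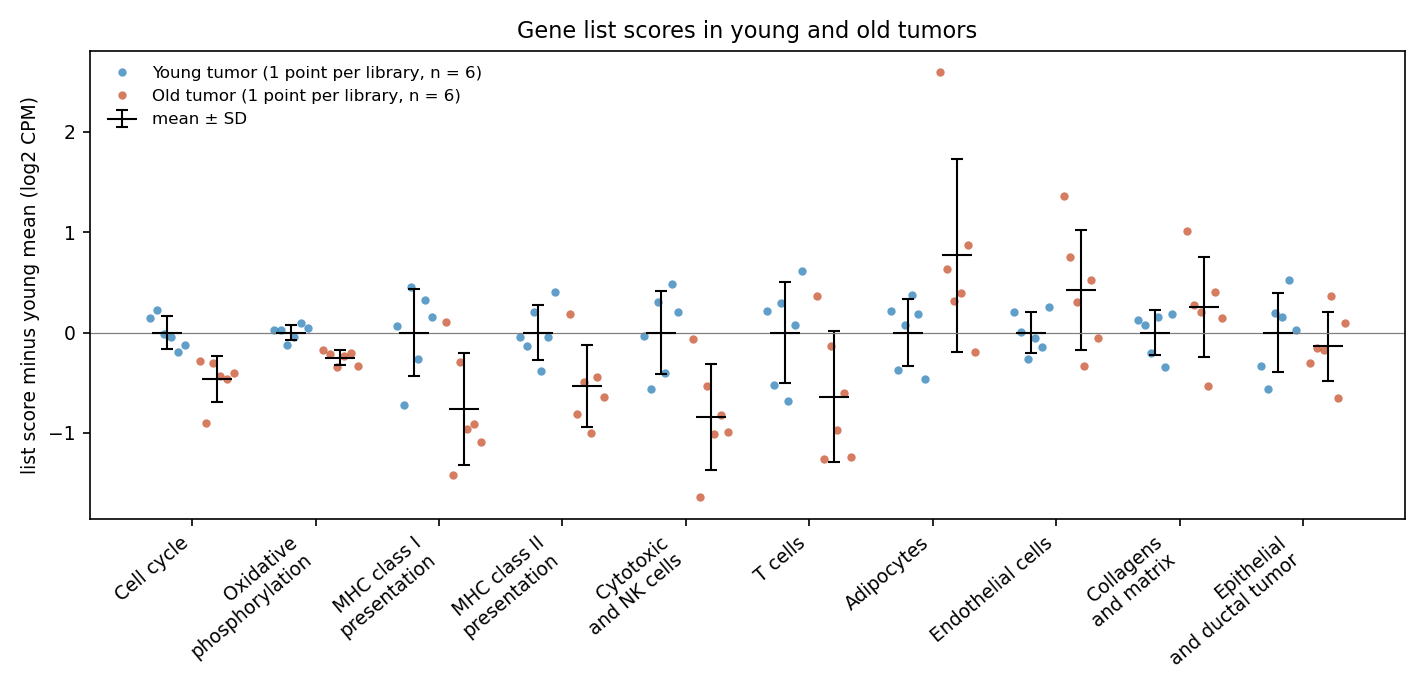
Scores of 10 gene lists in each library, as mean log2 CPM over members minus the mean of the young libraries, with 1 point per library and bars for the mean ± SD of 6 libraries. The cell cycle and oxidative phosphorylation lists lay lower in every old library than in any young one, while the T cell, adipocyte and endothelial lists overlapped between ages.

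Stromal and fat cell markers lay higher in old tumors on average without passing as lists. The adipocyte list differed by 0.77 (two-sided exact permutation p = 0.0541, adjusted p = 0.250). Of its 15 genes 8 passed the filter and were tested, all of them above 0. Plin4 rose over all genes and 5 members rose when adjusted over the list alone, among them Cidec (1.07, SE 0.33), Car3 (4.65, SE 1.61) and the hormone-sensitive lipase gene Lipe (0.36, SE 0.14). Old tumor 1 had the highest adipocyte score, and without it the difference lay at 0.39. The myofibroblastic list differed by 0.30 (two-sided exact permutation p = 0.305, adjusted p = 0.565); Itga11 and Col12a1 were the 2 of 17 members that rose, over all genes and when adjusted over the list alone, and Col12a1 lost its call with the length trend removed (edgeR adjusted p = 0.080). Its members Myl9 and Acta2 were at 0.93 (SE 0.41) and 0.84 (SE 0.43). Without Old tumor 4 the list differed by 0.50 and passed, and without Old tumor 1 it differed by 0.10 (exact permutation, adjusted p = 0.040 and 0.817). The pan-fibroblast list differed by 0.36 (adjusted p = 0.565) with all 18 members above 0, and collagens and matrix by 0.25 (adjusted p = 0.565) with 26 of 29 above 0, both by exact permutation. Neither held a gene that passed over all genes, and adjusted over the list alone 1 matrix gene, Col6a1, rose (0.42, SE 0.11). Endothelial markers differed by 0.42 (exact permutation, adjusted p = 0.407), where the endothelial cadherin gene Cdh5 was the member that rose when adjusted over the list alone (1.08, SE 0.30). Pericyte and smooth muscle markers differed by 0.48 (exact permutation, adjusted p = 0.475), with none of 12 members past either threshold. Without Old tumor 1 the differences were 0.11 for pan-fibroblast, 0.083 for matrix, 0.22 for endothelial and 0.16 for pericyte markers. Without Old tumor 4 the pan-fibroblast difference was 0.55 and the matrix difference 0.41. Matrix genes were long, at a median of 6809 bp, and with the length trend removed their difference was 0.16 (exact permutation, adjusted p = 0.707). Inflammatory fibroblast markers differed by 0.03 and mesothelial markers by 0.16 (exact permutation, adjusted p = 0.948 and 0.818).

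B cell and plasma cell markers did not pass as lists. The B cell list differed by 0.40 (two-sided exact permutation p = 0.0952, adjusted p = 0.320), with all 6 old libraries above the young median. Of its 15 genes 6 passed the filter and were tested, all of them above 0. Without Old tumor 1 the B cell difference was 0.20. The plasma cell list differed by 0.44 (exact permutation, adjusted p = 0.778); of its 12 tested members Ighm rose over all genes, and Ighm and Pou2af1 (1.60, SE 0.51) rose when adjusted over the list alone. Ighg1, the immunoglobulin G1 heavy chain gene, was at −2.81 (SE 1.29) and Jchain at 1.69 (SE 0.78). The plasma cell difference was 0.27 without Old tumor 1, 0.28 without Old tumor 2 and 0.26 without Old tumor 4. With medians over members it was 0.16, and the B cell difference 0.26. The plasma cell difference was 0.73 without Young tumor 5, 0.81 without Young tumor 6, 0.87 without Old tumor 3 and 0.93 without Old tumor 6. Acinar markers differed by −0.79 (two-sided exact permutation p = 0.0346, adjusted p = 0.214). Their level was low, at 1.29 ± 0.74 log2 CPM in young and 0.50 ± 0.40 in old tumors (SD, n = 6 each). Of 24 genes in the list 6 were tested, and Reg1 was the 1 that fell when adjusted over the list alone (−2.38, SE 0.75). Whether the list reports residual pancreas was not tested. The acinar difference was −1.35 over members of at least 1 CPM, and ran from −1.18 to −0.53 with 1 library left out. Epithelial and ductal tumor markers differed by −0.14 (exact permutation, adjusted p = 0.778), with none of 23 members past either threshold. It was −0.023 without Old tumor 5, −0.034 without Young tumor 5, −0.24 without Old tumor 4 and −0.26 without Young tumor 2. On log2(TPM + 1) it was −0.0050, and with medians over members −0.28. The senescence and secretory list differed by −0.20 (exact permutation, adjusted p = 0.475), with −0.31 without Old tumor 1, −0.13 without Old tumor 3 and −0.047 on log2(TPM + 1). Its member Cdkn2a fell over all genes and when adjusted over the list alone (−0.38, SE 0.087, edgeR adjusted p = 0.044).

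No other list passed. By exact permutation with adjusted p of 0.565 each, the differences were −0.31 for the type I interferon response, −0.24 for dendritic cells and −0.22 for NF-kB inflammatory genes. The list differences were −0.31 for neutrophils (adjusted p = 0.634), −0.22 for regulatory T cells (adjusted p = 0.634), 0.12 for macrophages and monocytes (adjusted p = 0.818) and 0.19 for complement (adjusted p = 0.818), all by exact permutation. They were −0.05 for the TGF-beta response, −0.06 for immediate early and heat shock genes, −0.01 for epithelial-mesenchymal transition and −0.0046 for hypoxia and glycolysis, with the smallest adjusted p among them at 0.572. With 1 library left out the TGF-beta difference ran from −0.11 to −0.0028 and that of immediate early genes from −0.093 to −0.023. With medians over members the TGF-beta difference was −0.28. Markers of lymphoid tissue chemokines (−0.16), Schwann cells (−0.04), erythrocytes (0.19) and islet cells (0.20) had adjusted p of 0.818 or above by exact permutation. The median member of the lymphoid list lay at 0.09, opposite in sign to its mean. Without Old tumor 1 the differences were −0.48 for type I interferon, −0.42 for dendritic cells, −0.34 for NF-kB, −0.53 for neutrophils and −0.41 for regulatory T cells. Type I interferon lay at −0.20 without Old tumor 2, dendritic cells at −0.15 without Old tumor 4, and NF-kB at −0.36 without Young tumor 2 and −0.13 without Old tumor 5. Neutrophils lay at −0.49 without Young tumor 2, −0.12 without Young tumor 3 and −0.18 without Old tumor 6, and regulatory T cells at −0.14 without Young tumor 6 and −0.12 without Old tumor 3. On log2(TPM + 1) the differences were −0.14 for type I interferon, −0.023 for dendritic cells, −0.079 for NF-kB and −0.16 for neutrophils. With medians over members they were −0.58 for type I interferon, −0.034 for NF-kB and −0.66 for neutrophils. No member of any list in this paragraph passed over all genes with edgeR or when adjusted over the list alone.

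The T cell score was compared with the neutrophil, matrix and epithelial scores across the 12 tumors, 3 relations in all. T cell and neutrophil scores rose together, with Pearson r = 0.781 (permutation p = 0.00335, adjusted p = 0.010) and Spearman rho = 0.769 (permutation p = 0.00514, adjusted p = 0.0154). Other leukocyte lists were not compared with the T cell score, so the relation is not shown to be particular to neutrophils. Within the young tumors r was 0.822 and rho 0.829 (n = 6, exact permutation p = 0.050 and 0.0583), and within the old tumors r was 0.771 and rho 0.543 (n = 6, exact permutation p = 0.0569 and 0.297). Without Young tumor 3 and Old tumor 1, the libraries farthest from the median neutrophil score, r was 0.739 and rho 0.648 (permutation, adjusted p = 0.0449 and 0.148). On log2(TPM + 1) r was 0.717 and rho 0.559 (permutation, adjusted p = 0.0282 and 0.190), so the rank relation lost its call in both. T cell and matrix scores gave r = 0.179 and rho = 0.0490 (permutation p = 0.589 and 0.885), and r = −0.427 without Old tumor 1 and Old tumor 4 (permutation p = 0.225). Within the young and the old tumors that r was −0.159 and 0.659 (n = 6 each, exact permutation p = 0.832 and 0.175). T cell and epithelial scores gave r = −0.0041 and rho = −0.0909 (permutation p = 0.989 and 0.782), with r = 0.235 in young and −0.447 in old tumors (n = 6 each, exact permutation p = 0.651 and 0.388) and r = −0.228 without Old tumor 5 and Young tumor 5.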

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

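Among 126 sets of 6 libraries (list scores, named genes, library totals and length slopes within an age group), 10 held a library whose gap to its nearest neighbor exceeded 0.625 of the whole range. Chance gives about 1 in 20 such sets. The B cell list score of Old tumor 1 was 2.63 log2 CPM, against 1.44 to 1.56 in the other old libraries. Old tumor 2 lay lowest among old libraries for the cell cycle list, at 4.70 against 5.14 to 5.32 log2 CPM, for Nek2, at 2.74 against 3.40 to 3.62, and for Rrm2, at 4.33 against 4.90 to 5.23. Hoxb3 in Old tumor 4 was at 0.59 log2 CPM, against 1.59 to 2.10 in the other old libraries. The hypoxia and glycolysis score of Young tumor 5 was 8.03, against 7.005 to 7.35 in the other young libraries. Young tumor 2 lay lowest among young libraries for the NF-kB inflammatory score, at 3.02 against 3.75 to 4.03, for Plin4, at −0.064 against 0.999 to 1.57, and for Prelp, at 3.42 against 4.001 to 4.22 log2 CPM. Old tumor 6 had 17.8M counts, against 23.3M to 24.1M in the other old libraries.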

How the results depend on the processing

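The corrections for length and GC content and the removal of Old tumor 1 with Old tumor 5 were chosen after the data were seen. The genes called, 127 higher and 235 lower, moved by over 1.5 times under many settings. DESeq2 called 569 and 864, limma-voom 418 and 559, an adjusted p under 0.10 gave 530 and 726, and the fit without Old tumor 1 and Old tumor 5 gave 343 and 399. Without a filter 41 and 110 passed, and at least 2-fold 14 and 5. The stricter filter gave 364 lower, total counts 143 lower. TPM gave 291 higher and 48 lower with a pseudocount of 1, and 312 and 44 with 0.1. Length correction gave 15 and 97, GC correction 73 and 354, and both together 12 and 83. The acinar covariate left 1 and 0 with edgeR (2418 genes at an unadjusted p under 0.05). That score rested on 6 genes of low level and itself differed by −0.79 between the ages, so the covariate and age overlap. Leaving out 1 library gave 2 to 433 higher and 0 to 673 lower genes. Without Old tumor 3, where 2 genes passed with edgeR, 2873 of the genes tested with all libraries still had an unadjusted p under 0.05, so the calls moved more than the number of small p-values did. Libraries with the same replicate number did not deviate together on average (mean correlation −0.0015, from −0.230 to 0.139, and 2 of 6 correlated best with their own number). These 6 correlations gave no sign of a pairing but cannot exclude one, and the labels leave it open. As a replicate block the number left 1 higher and 0 lower genes with edgeR, with and without the length correction (2408 and 3056 genes at an unadjusted p under 0.05). The 24 named genes kept their direction wherever they were tested, and Igkv3-2 was not tested under the stricter filter. All 24 kept their call with DESeq2, RLE factors and GC correction, 14 with length correction, and 0 with the acinar covariate or the block. With 1 library left out, 24 kept it without Old tumor 1 and 21 without Young tumor 3. At most 8 kept it without any other library, with 0 without Young tumor 1, 1 without Old tumor 3 and 2 without Old tumor 5.

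Of the 2 lists called, 2 were called under RLE factors, the stricter filter, fry, length or GC correction and members of at least 1 CPM. Camera called 16 with the preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05), and 0 to 5 were called with 1 library left out. By exact permutation 0 were called on total counts, TPM, medians over members and same-numbered differences under the block (8, 6, 8 and 5 lists at an unadjusted p under 0.05), where the block allows no p under 0.0313. The cell cycle difference of −0.46 was −0.43, −0.30, −0.46 and −0.46 there, and that of oxidative phosphorylation −0.22, −0.13, −0.28 and −0.25. With 1 library left out they ran from −0.52 to −0.38 and from −0.28 to −0.23. Lists near 0 changed sign without being called in any setting, and the cause was not tested. On TPM these were immediate early (0.074), regulatory T cells (0.068), TGF-beta (0.088), Schwann cells (0.035), mitochondrially encoded (0.076), epithelial-mesenchymal transition (0.096) and hypoxia (0.13). With medians they were senescence (0.029), mesothelium (−0.12), lymphoid chemokines (0.0098), islet cells (−0.013) and epithelial-mesenchymal transition (0.14). With the stricter filter they were regulatory T cells (0.029), mesothelium (−0.020), islet cells (−0.11) and inflammatory fibroblasts (−0.012). Regulatory T cells lay at 0.038 with members of at least 1 CPM, mitochondrially encoded genes at 0.061 with length correction, epithelial-mesenchymal transition at 0.017 and hypoxia at 0.026 on total counts. With 1 library left out complement ran from −0.073 to 0.36, macrophages from −0.092 to 0.24, mesothelium from −0.098 to 0.37, lymphoid chemokines from −0.45 to 0.0027, Schwann cells from −0.10 to 0.025, mitochondrially encoded genes from −0.18 to 0.018, erythrocytes from −0.065 to 0.51, islet cells from −0.27 to 0.70, inflammatory fibroblasts from −0.25 to 0.24, epithelial-mesenchymal transition from −0.13 to 0.078 and hypoxia from −0.081 to 0.13. The T cell relation to the epithelial score was r = 0.0018 on total counts.

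Among 100 splits of the 12 libraries into 6 and 6, only 1, the real one, gave 362 genes or more, and the highest other gave 0. With the length correction only 1 gave 112 or more, and the highest other gave 2. Among the splits tried, a random grouping thus did not reach either count, though not all 462 splits were run for them. For the 2 lists, 10 of all 462 splits gave as many, a share under 0.05. Some splits of mixed age gave more lists than the real one, so this count alone does not set age apart. The highest other gave 11, with Old tumor 1 placed among the young and Young tumor 2 among the old libraries, which points to a structure of the samples. Whether correlation among the lists alone gives as many was not tested. Library depth, at 17.8M to 24.1M counts, was not varied.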

Other observations

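The immunoglobulin shares, the genes outside the naming rule, the tests of RNA integrity, of length on the MHC class I list, of the neighbors of Gm10600 and of copies near it were chosen after the data were seen.

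The mix of antibody classes differed between the ages. Of the counts of 8 heavy chain constant genes, Ighm took 10.9% ± 7.16 in young and 75.7% ± 21.1 in old tumors (SD, n = 6 each; two-sided exact permutation p = 0.00216, adjusted p = 0.00758 over 7 measures). Ighm shares ran from 1.63% to 19.96% in young and from 46.0% to 97.0% in old libraries, with no overlap. Igha, the immunoglobulin A gene, took 32.8% ± 13.9 in young and 5.78% ± 4.26 in old tumors (SD, n = 6 each; exact permutation, adjusted p = 0.00758). Ighg1 took 49.7% ± 20.7 and 4.52% ± 10.01 (SD, n = 6 each; exact permutation, adjusted p = 0.0101), with 24.9% in Old tumor 4 and at most 1.63% in the other old libraries. Shares of one sum fall when Ighm rises, and the levels of Igha and Ighg1 themselves did not pass (log2 fold change −1.09, SE 0.79, and −2.81, SE 1.29; edgeR adjusted p = 0.449 and 0.229). The summed heavy chain level was 112 ± 123 CPM in young and 317 ± 335 CPM in old tumors (SD, n = 6 each; exact permutation, adjusted p = 0.273). Ighg2b, Ighg2c and Ighg3 shares did not pass (exact permutation, adjusted p = 0.931, 0.702 and 0.524). The gamma constant genes resemble one another, so the split among them is uncertain.

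Among called genes outside the lists, the enzymes of isoprenoid synthesis Idi1 and Fdps fell by 0.65 (SE 0.12) and 0.52 (SE 0.10), and both passed with the length correction too (edgeR adjusted p = 0.041 and 0.043). The ribosomal protein gene Rps21 fell by 0.56 (SE 0.10) and the splicing factor gene Lsm4 by 0.48 (SE 0.071). The endocytic receptor gene Lrp1 and the perlecan gene Hspg2 rose by 0.64 (SE 0.12) and 0.62 (SE 0.13), and neither passed with the length correction (edgeR adjusted p = 0.088 and 0.090). Of all tested genes 160 were higher in every old than in every young library and 315 lower, where chance gives 0.216% of the 16013 tested genes in both directions together.

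Long genes were higher and short genes lower in old tumors, with a difference in length slope of 0.0696 (SE 0.0178). Removing a GC trend from each library left it at 0.0715 (SE 0.0162), which argues against GC content as the whole cause. Leaving out 691 genes of protein synthesis and degradation, respiration and the cell cycle left it at 0.0646 (SE 0.0179). Those were a small part of the 15971 genes with a length, so a large fall was unlikely from the start. The slope thus does not rest on those genes alone. Slopes of young libraries alone spanned 0.0924. A range over single libraries is not the same measure as a difference of group means, and it does not show what made the libraries differ. It therefore cannot decide whether RNA integrity or fragment size adds to the trend. Integrity values for single libraries were not used here, so RNA integrity or fragment size and a biological effect of host age cannot be told apart. Removing the trend left 15 of 127 higher and 83 of 235 lower calls, while the median log2 fold changes went from 0.47 to 0.33 and from −0.41 to −0.38.

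The MHC class I list lay lower in old tumors by 0.76 on the log2 scale without passing adjustment. With the epithelial score as a covariate the difference was −0.73 (SE 0.31), and with the length trend removed it was −0.77 (SE 0.27), which argues against tumor cell share and gene length as the whole cause. With the T cell score as a covariate it was −0.27 (SE 0.16), so part of the difference moved with that score. A covariate cannot show whether T cells themselves carry or cause the lower list. The 2 scores move together and the remainder exceeds its standard error, so T cell content and a separate effect of host age cannot be told apart.

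Gm10600, a predicted gene (ENSMUSG00000083929; chromosome 4, 42240639 to 42242685, mm10), had 21 to 75 counts in every old library and 0 to 1 in the young ones (edgeR adjusted p = 3.3e-04). The 5 other genes with counts within 50 kb were together 11.8 times higher in old tumors. Of 26 other genes with counts within 0.4 Mb the largest loss in old tumors was −10 counts, against the 227 that Gm10600 gained, which argues against reads moved between nearby annotated copies. The log2 fold change of Nnt, a gene partly deleted in a common C57BL/6 substrain, was −0.089 (SE 0.13), which does not settle whether the mice differed in substrain. A germline difference between the sources of young and old mice may underlie the locus, but every old library carried the counts, so source and age cannot be told apart. Pydc3 (ENSMUSG00000066677; chromosome 1, 173673675 to 173698395), an interferon-inducible gene of another repeated cluster, had 11 to 33 counts in old and 0 to 3 in young libraries (edgeR adjusted p = 0.014).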
